A study of Arabidopsis thaliana with 21 samples.

How the data were processed

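RNA was measured in 21 libraries of wild-type Arabidopsis thaliana seeds. Per the labels' protocols these were stranded polyA libraries read from 1 end, from seeds under long days. Groups and replicate numbers were taken from the sample titles, which name ethylene or water at 6, 16 or 24 h, or dry seeds, with 3 replicates in each of the 7 groups. The treatment label of the water samples states no treatment, and a part of the dry samples' titles could not be interpreted and was not used.

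The deposited values were raw read counts per gene for each library, 37336 genes in each. The authors aligned reads and counted them per gene with STAR against the build TAIR10, per the submitters' processing notes, and the STAR version, annotation release and trimming were not given in the sources used here. The deposited files held 3 counts per gene, for reads on either strand, in forward and in reverse orientation, per the file headers. The reverse-strand counts held the sense reads of this kit and were used here. The forward counts held 2.72 to 5.41% of the forward and reverse gene reads together and served only as a check. Counts of near-identical gene copies, such as those of light-harvesting proteins, are uncertain, because reads that matched more than 1 place were not counted on genes. The 4 summary lines of each library were left out of library sizes and tests: multimapping reads made up 1.44 to 2.47%, reads on no gene 0.752 to 2.78%, ambiguous reads 0.0776 to 0.166% and unmapped reads 0.209 to 2.04%. Gene symbols came from a reference table of the assembly TAIR10.1, which matched 37051 genes. Because its build differs from that of the counts, no coordinates were used.

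Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, 2-sided, with TMM scaling, the default expression filter (minimum count 10, total 15) and Benjamini-Hochberg adjustment over all genes tested, at an FDR of 0.05. The 18 imbibed libraries formed 1 fit with 18806 genes, used for ethylene against water at each time and for the change of that difference between times. The 12 dry and water libraries formed another fit with 17782 genes. The biological coefficient of variation of the second was 0.0509. CPM were scaled within each fit, so a group has different CPM in the 2 fits, and they are given as mean ± SD over 3 libraries. The SE of a log2 fold change was approximated as its size over the square root of F. A fold against a group with 0 counts was computed against a floor of 3 counts over the group and is given as a lower bound. For 1 to 3 counts the ratio of counts per library size is given with a 95% exact counting interval. Intervals and floors cover counting error only.

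Gene lists, 27 with 464 members in all after 3 were dropped for conflicting symbols, covered ethylene synthesis, perception and response factors, abscisic acid synthesis, catabolism and signalling, and gibberellin synthesis, inactivation and signalling. They also covered dormancy regulators, storage proteins and oleosins, late embryogenesis abundant proteins, cell wall loosening, the cell cycle, beta-oxidation with the glyoxylate cycle and gluconeogenesis, photosynthesis, the low-oxygen response, the N-degron pathway and reactive oxygen enzymes. The rest were auxin, cytokinin, jasmonate and salicylate responses, heat shock proteins, markers of endosperm, embryo and seed coat, and 92 cytosolic ribosomal protein genes chosen by product name. Lists with at least 3 tested members were tested with camera (limma 3.58.1, voom weights, preset correlation 0.01), adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests a list on its own and not against other genes, were run beside it. Calls were also counted with p-values adjusted over the list alone. Members at 0 in a group have a fitted fold change that depends on the prior count, so list medians were also computed with these members at their bound. Of 162 list medians 26 held such members, and the largest move was 2.17 on the log2 scale. The sign changed in 0, but a member at its bound kept its direction, which left little room for such a change. Overlaps between times were compared with the number from independent lists and with Fisher's exact test.

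The groups, tests, lists, alternatives and the rule for naming genes of the report were fixed before the data were examined. The rule took, for ethylene against water, the 6 genes with the largest increase and the 6 with the largest decrease among those called, with a mean log2 CPM of at least 1, no overlap between groups and a symbol. It added up to 4 called members of each list and 15 sentinel genes whatever their p, of which 1 is not reported here. For water and dry seeds it took 4 and 4 genes and up to 2 per list, and for changes between times 4 and 4 without the overlap condition. Genes of light-harvesting, leaf and light-response sets in single water libraries, and ERS2, EBF2, ETR2 and NCED6 in the change between times, stand outside that rule and were named after their values were seen.

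Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0 with and without independent filtering, no filter and a stricter filter (CPM of 1 in 3 libraries), only the compared groups, all 21 libraries, the replicate number as a block, an FDR of 0.01 and leaving out each library in turn. Fits without the library labelled ethylene 16 h replicate 2 in comparisons that do not use it, unstranded counts, and the photosynthesis list without water 24 h replicate 3 were added after the data were seen. Libraries were compared by correlation and by a chi-square test over genes with at least 10 reads. Within groups the chi-square per degree of freedom was 1.69 to 7.86, apart from the pairs with the library labelled ethylene 16 h replicate 2, which gave 328.7 and 357.2 against the other ethylene 16 h libraries and 2.77, 1.39 and 3.66 against water 16 h replicates 1, 2 and 3, and no library was a copy of another.

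The tests were checked on simulated counts with 200 changed genes. For ethylene against water at 6 h, over 18228 genes, 40, 70, 94 and 96% of genes changed 1.5-, 2-, 4- and 8-fold were recovered, and 72, 90, 100 and 100% with the spread taken without the library labelled ethylene 16 h replicate 2 (18184 genes). At 16 h (18214 genes) the shares were 40, 80, 94 and 100%, and at 24 h (18172 genes) 32, 72, 98 and 100%. For water at 24 h against 16 h (17232 genes) they were 90, 100, 100 and 100%, and 10.6% of the calls were of unchanged genes, above the nominal 5%. In the other simulated comparisons that share was 1.31 to 6.49%. Simulated genes varied independently and changed in all 3 libraries of the group. In the real ethylene 16 h group 1 library lay at the water level across genes. The simulated recovery at 16 h therefore does not describe that comparison. The real tests called 14997 of 18806 genes at 24 h and 7601 to 14163 of 17782 in the dry and water comparisons. Scaling and adjustment under such broad change were not tested with 200 changed genes. The spread from all libraries at 6 h and 24 h includes that library. The biological coefficient of variation was 0.187 with it and 0.0436 without it. The simulated shares of these comparisons therefore need not hold for the real genes. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.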

Results

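Transcript levels were measured by RNA sequencing in wild-type Arabidopsis thaliana seeds, in 21 libraries that formed 7 groups of 3. The groups were dry seeds and seeds imbibed for 6, 16 or 24 h, either in water or with ethylene, a gaseous plant hormone. The series title names the effect of ethylene as the subject, and the design text names treated against untreated seeds. That text calls the replicates biological, but nothing says that they came from separate seed lots, so p-values here measure only the spread between these samples, which may be technical. Each library held 12154732 to 22109880 reads, of which 94.3 to 97.4% were counted on genes. The shallowest libraries were water 24 h replicate 1 with 12154732 reads and water 6 h replicate 1 with 13646486. The 10 most abundant genes took 20.3 to 20.7% of the gene reads in dry seeds, 15.4 to 16.5% in water at 24 h and 6.95 to 7.23% with ethylene at 24 h.

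The first 2 principal components of 15480 genes held 66.3% and 18.4% of the variance, and the replicates of each group lay together except for 1 library. The library labelled ethylene 16 h replicate 2 lay among the water 16 h libraries, at 7.82 on the first component, while the other ethylene 16 h libraries lay at 121 and 125. Its log2 levels correlated across genes at 0.9945 to 0.996 with the water 16 h libraries and at 0.818 to 0.827 with the other ethylene 16 h libraries. It was kept in the analysis that follows, because its label places it there, and each leading count is also given without it. With this library the biological coefficient of variation of the fit was 0.187, and without it 0.0436.

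**Figure D1:**
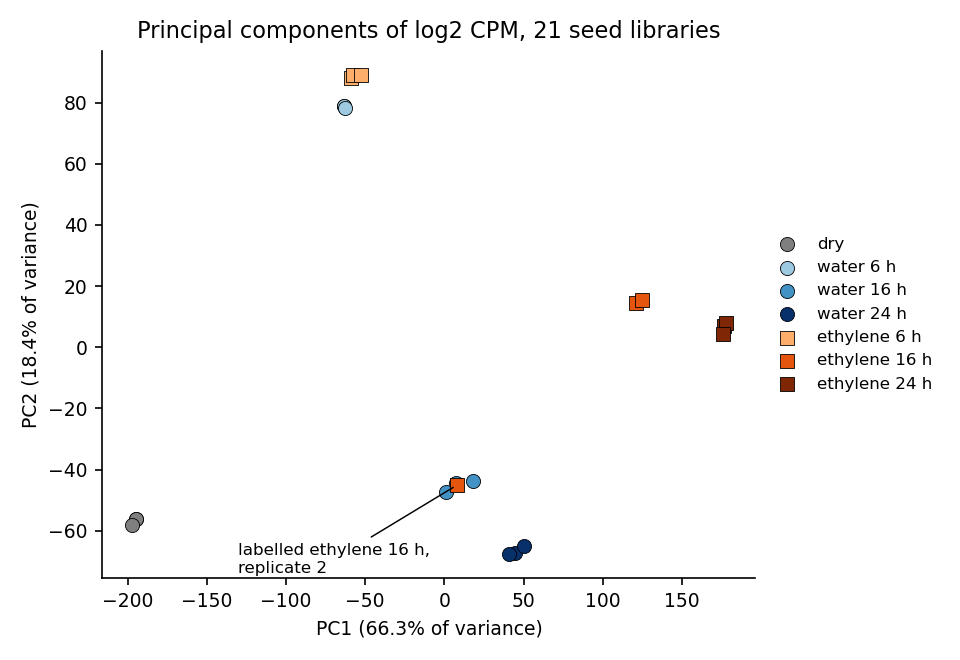
Principal component scores of the 21 libraries from log2 CPM of 15480 genes, with component 1 (66.3% of the variance) on the horizontal axis and component 2 (18.4%) on the vertical axis, and 1 symbol per library marked by group. The library labelled ethylene 16 h replicate 2 sits with the water 16 h libraries at 7.82 on component 1, away from the other ethylene 16 h libraries at 121 and 125.

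Ethylene was compared with water at 6 h to find the earliest response among the times measured. Among the genes named here the largest increases were in 2 genes of the ethylene response, ARGOS and ERF1. ARGOS (AT3G59900), which lowers ethylene sensitivity, was at 40.9 ± 2.24 against 0.513 ± 0.331 CPM (mean ± SD, n = 3 per group, ethylene first), a log2 fold change of 6.2 ± 0.98 (± SE). The transcription factor genes ERF1 (AT3G23240) and ERF2 (AT5G47220) rose 15.5-fold and 4.65-fold, to 7.14 ± 0.258 CPM and 24.4 ± 2.21 CPM. The ethylene receptor gene ERS2 (AT1G04310) rose 4.62-fold, from 4.89 ± 0.544 CPM to 22.5 ± 1.51 CPM. Below water lay CYP709B2 (AT2G46950), a cytochrome P450, at 2.0 ± 0.396 against 7.74 ± 1.39 CPM, and DWF4 (AT3G50660), an enzyme of brassinosteroid synthesis, at 3.18 ± 0.0763 against 7.19 ± 0.463 CPM.

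Among the other genes with the largest changes at 6 h, the NAC factor gene NAC6 rose 6.78-fold and the flagellin receptor gene FLS2 5.94-fold. The amino acid transporter gene SIAR1 lay 4.05-fold lower, ASG8 2.65-fold, TBL22 2.47-fold and the nitrate transporter gene NRT2.6 2.46-fold lower, each past the threshold. Of 14 tested genes of ethylene perception and signalling 6 rose and 0 fell (10 and 0 adjusted over the list alone), with a median log2 fold change of 0.80 and a camera adjusted p of 7.05e-17, or adjusted p = 0.0344 with an estimated correlation. They included RTE1, a regulator of the receptor ETR1 (2.15-fold), the kinase gene CTR1, a negative regulator of the pathway (252 ± 2.41 against 144 ± 3.22 CPM), and EBF2, whose product removes EIN3 (626 ± 2.15 against 361 ± 18.7 CPM). Of 13 tested ethylene response factor and ethylene-induced genes 2 rose and 0 fell (3 and 0 adjusted over the list alone; median 1.39, camera adjusted p = 0.000105, adjusted p = 0.255 with an estimated correlation). When the library labelled ethylene 16 h replicate 2 was left out, 12 perception genes rose and 1 fell (adjusted p = 0.000173 with an estimated correlation), and 7 response genes rose and 1 fell (adjusted p = 0.0025 with an estimated correlation). The receptor gene ETR2 (AT3G23150) stood at 199 ± 4.92 against 42.7 ± 1.68 CPM, a log2 fold change of 2.22 ± 0.55, with an adjusted p of 0.0894 in edgeR's quasi-likelihood test, and 1.03e-22 without the library labelled ethylene 16 h replicate 2.

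With all 18 libraries the remaining lists held few calls at 6 h, and none passed camera. A further 6 lists passed without the library labelled ethylene 16 h replicate 2. Late embryogenesis abundant genes fell in 9 (camera adjusted p = 1.51e-12), storage genes in 3 and heat shock genes in 2 (camera adjusted p = 9.34e-05 each) and reactive oxygen enzymes in 2 (camera adjusted p = 0.0185), while ribosomal protein genes rose in 3 (camera adjusted p = 0.000263) and dormancy regulators in 2 (camera adjusted p = 0.0107). Their medians lay between -0.33 and 0.10, and they had adjusted p = 0.0683 to 0.468 with an estimated correlation. Of the abscisic acid signalling genes 5 then rose and 5 fell. With all 18 libraries GA20OX3, of gibberellin synthesis, lay 1.62-fold lower (147 ± 6.73 against 238 ± 19.2 CPM), the mannanase gene MAN7 of the endosperm and cell wall lists 2.24-fold lower, and the root patterning gene SCR 1.31-fold lower. RAP2.2, a factor of the N-degron pathway, rose 1.43-fold. Genes of abscisic acid, storage and dormancy were not called in that fit. Log2 fold changes were -0.34 for CYP707A2, -0.28 for ABI5, 0.29 for DOG1, -0.16 for RGL2, -0.10 for CRA1 and -0.30 for EM6. They were -0.20 for GA3OX1, 0.37 for GA3OX2, -0.11 for ADH1 and -1.21 for EXPA2. A missing call in that fit does not show that a gene was unchanged. EXPA2 lay at 2.87 to 3.79 CPM with ethylene against 7.1 to 8.74 in water, and EM6 at 1132 to 1234 against 1436 to 1486. The CPM of GA3OX1, GA3OX2 and ADH1 overlapped between the groups. NCED6 had 3 counts with ethylene and 16 in water, a ratio of 5.89 with a 95% counting interval of 1.69 to 31.6.

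At 6 h edgeR's quasi-likelihood test called 107 genes higher and 68 lower among 18806 tested, and 56 of the higher and 15 of the lower changed at least 2-fold. Without the library labelled ethylene 16 h replicate 2 the counts were 906 and 944, of which 214 and 73 changed at least 2-fold. DESeq2 called 301 genes, a fit on the compared groups alone 2325, and an FDR of 0.01 left 79. Leaving out ethylene 6 h replicate 1, 2 or 3 gave 89, 96 or 99 genes, and leaving out water 6 h replicate 1, 2 or 3 gave 106, 93 or 84.

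At 16 h single genes of hormone synthesis differed, although the lists of ethylene, gibberellin and abscisic acid synthesis did not pass camera (adjusted p = 0.818, 0.581 and 0.172). ACO1 (AT2G19590), encoding an enzyme of the last step of ethylene synthesis, rose 101-fold over a water mean of 2.86 ± 1.53 CPM. GA3OX2 (AT1G80340) and GA3OX1 (AT1G15550), which encode the last step to active gibberellin, rose 29-fold and 7.74-fold. The expansin gene EXPA1 rose 10.3-fold and the xyloglucan-modifying gene XTH33 27.5-fold. NCED9 (AT1G78390) of abscisic acid synthesis fell to 3.63 ± 4.84 against 10.1 ± 0.463 CPM. All ethylene 16 h means include the library labelled replicate 2, which widened their SDs: ETR2 (AT3G23150) was at 126 ± 96.3 against 16.7 ± 1.24 CPM, with a log2 fold change of 2.92 ± 0.56, and of 3.44 without that library. NCED9 was then at -3.58 and ACO1 at 7.25.

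The largest increases at 16 h also held ARGOS (135-fold), the transcription factor genes NAC047 (61.1-fold) and WRKY65 (22.1-fold), the sucrose transporter gene SUC5 (17.1-fold), ST2B (16.5-fold), TBL28 (14.3-fold) and FLS2 (13.6-fold). The decreases that met the naming rule held CYP71B12 (5.46-fold), the vesicle protein gene VAMP712 (3.4-fold), the jasmonate synthesis gene AOS (3.16-fold), UGT85A5 (3.09-fold) and the glyoxalase gene GLYI4 (3.02-fold), and without the library labelled replicate 2 these folds were 24.8, 28.5, 12.5, 13.8 and 7.77. With that library at the water level, the threshold and the no-overlap condition left out genes with larger decreases in replicates 1 and 3. EM6 was at 50.2 and 38.7 CPM in ethylene replicates 1 and 3 and 2208 in replicate 2, against 2018 to 2651 in water. GSTU22 had 2 counts with ethylene and 12 in water, a ratio of 6.64 (95% counting interval 1.48 to 61.1), and was not called without ethylene 16 h replicate 1 or 3 or water 16 h replicate 3. VAMP712 passed the threshold narrowly and did not pass without any 1 of the other 5 compared libraries. On the log2 scale VAMP712 was at -1.17 and CYP71B12 at -1.81 without ethylene 16 h replicate 3, SUC5 at 3.51 without ethylene 16 h replicate 1, TBL28 at 4.43 and WRKY65 at 6.23 without water 16 h replicate 1, and WRKY65 at 3.87 without water 16 h replicate 3.

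Of 14 ethylene perception genes 10 rose and 1 fell at 16 h (the same counts adjusted over the list alone; median 0.68, camera adjusted p = 0.0483), among them ERS1 (7.02-fold), ERS2 (1.88-fold) and EBF2 (1.2-fold). Cell wall loosening genes rose in 15 of 20 and fell in 0 (15 and 0 adjusted over the list alone; median 2.14, camera adjusted p = 0.031), with EXPA2 at 197 ± 128 against 52.6 ± 22.4 CPM. Genes of beta-oxidation, the glyoxylate cycle and gluconeogenesis rose in 13 of 18 and fell in 1 (13 and 1 adjusted over the list alone; median 0.53, camera adjusted p = 0.0014), with PCK1 rising 1.97-fold. Auxin response genes rose in 10 of 17 and fell in 0 (10 and 0 adjusted over the list alone; median 1.69, or 1.42 with members at 0 in water set to their bound, camera adjusted p = 0.0483). Cytosolic ribosomal protein genes rose in 57 of 82 and fell in 7 (60 and 9 adjusted over the list alone; median 0.43, camera adjusted p = 2.7e-05). These lists did not pass with a correlation estimated in the fit that keeps the library labelled ethylene 16 h replicate 2 (adjusted p = 0.631 with an estimated correlation for each). Camera calls were lost without water 16 h replicate 1 (perception adjusted p = 0.0735, auxin 0.0541), replicate 2 (both 0.0532) and replicate 3 (cell wall and auxin 0.0543).

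The seed reserve lists fell as groups at 16 h, although few single members passed the test. Storage protein and oleosin genes fell in 3 of 12 and rose in 0 (0 and 0 adjusted over the list alone; median -1.39, camera adjusted p = 3.57e-05), with SESA1 (AT4G27140), a 2S albumin, 2.4-fold and the cruciferin gene CRB 2.2-fold lower. Late embryogenesis abundant protein genes fell in 1 of 11, M10 (1.98-fold), and rose in 0 (0 and 0 adjusted over the list alone; median -1.46, camera adjusted p = 3.57e-05). Heat shock genes fell in 3 of 12 and rose in 0 (0 and 0 adjusted over the list alone; median -1.02, camera adjusted p = 0.000317). Each of these 3 lists had an adjusted p = 0.631 with an estimated correlation, in the fit that keeps the library labelled ethylene 16 h replicate 2. Without the library labelled ethylene 16 h replicate 2, 12 of 12 storage, 11 of 11 late embryogenesis abundant and 10 of 12 heat shock genes fell, with medians of -3.50, -4.51 and -2.04, and SESA1 was 6.7-fold, CRB 4.91-fold and M10 3.71-fold lower. CRA1, a cruciferin, was at 22329 ± 30527 against 57931 ± 6263 CPM (adjusted p 0.0975, and 6.89e-21 without that library) and EM6 at 766 ± 1249 against 2303 ± 322 CPM (adjusted p 0.179 and 5.45e-24).

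Lists not called by camera at 16 h held single changes. EDF3, an ethylene response factor gene, had 411 counts with ethylene and 2 in water, a ratio of 186 (51.1 to 1540), and TEM1 rose 14.5-fold. The gibberellin inactivation gene GA2OX3 had 765 counts against 1, a ratio of 692 (124 to 27400), and GA2OX2 fell 2.41-fold. The gibberellin-stimulated gene GASA6 rose 11.6-fold, the replication clamp gene PCNA1 6.15-fold, the haemoglobin gene HB1 11.1-fold and the root meristem gene PLT1 2.06-fold. CYP707A2, an abscisic acid 8'-hydroxylase gene, fell 2.38-fold, the germination repressor gene SOM 1.72-fold, the abscisic acid response gene ABI5 1.96-fold, the DELLA gene RGL2 1.24-fold and the endosperm gene EPR1 2.25-fold. These folds without the library labelled ethylene 16 h replicate 2 were 6.25, 2.7, 3.62, 1.41 and 5.23, and that of GA2OX2 6.24. Log2 fold changes that did not pass were -0.86 for NCED6, -0.98 for DOG1 and -0.38 for ADH1, and without that library these were -1.85, -1.57 and -0.66 and passed (adjusted p 2.95e-08, 0.00485 and 6.85e-08). Counts of members higher and lower were 4 and 0 of 9 for ethylene synthesis, 8 and 2 of 13 for ethylene response factors, 6 and 3 of 10 for gibberellin synthesis and 13 and 3 of 23 for the cell cycle. They were 11 and 7 of 25 for abscisic acid signalling, 3 and 5 of 13 for dormancy regulators and 10 and 1 of 15 for the low-oxygen response, which passed camera without that library (adjusted p = 0.0161, and adjusted p = 0.235 with an estimated correlation).

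At 16 h 5955 genes were called higher and 3485 lower (edgeR, 18806 tested), 2292 and 397 of them by at least 2-fold. Without the library labelled ethylene 16 h replicate 2 the counts were 8022 and 6245, of which 3452 and 2113 changed at least 2-fold, and 9425 genes were called in the same direction both ways. In a fit on the 6 compared libraries alone edgeR called 0 genes at an FDR of 0.05 and 3267 at an unadjusted p under 0.05, while DESeq2 in the fit of 18 libraries called 5907 higher and 4057 lower. Leaving out ethylene 16 h replicate 1 or 3 gave 1471 or 1064 genes (1421 higher and 50 lower, or 1027 and 37), and leaving out water 16 h replicate 2 or 3 gave 4978 or 3444 (4075 and 903, or 3112 and 332). An FDR of 0.01 left 2209 higher and 102 lower, so the balance of directions depended on the libraries and the threshold. Among fits leaving out 1 compared library, 56.2% of calls were higher without the library labelled replicate 2, against 71.9 to 96.6% in the others.

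At 24 h ethylene-treated seeds held far less storage and desiccation mRNA than seeds in water. The cruciferin gene CRA1 (AT5G44120) fell from 80056 ± 4189 CPM to 466 ± 101 CPM, a log2 fold change of -7.43 ± 0.88. The late embryogenesis abundant genes EM1 (AT3G51810) and EM6 (AT2G40170) fell 489-fold and 453-fold, the dehydrin gene RAB18 241-fold and the oleosin gene OLEO1 168-fold. The expansin gene EXPA2 (AT5G05290) rose from 95.4 ± 20.7 CPM to 725 ± 47.3 CPM and GA3OX2 (AT1G80340) from 1.85 ± 0.36 CPM to 20.2 ± 1.48 CPM. ABI5 (AT2G36270), a transcription factor of abscisic acid response, fell from 260.0 ± 6.93 CPM to 22.6 ± 1.24 CPM.

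**Figure D2:**
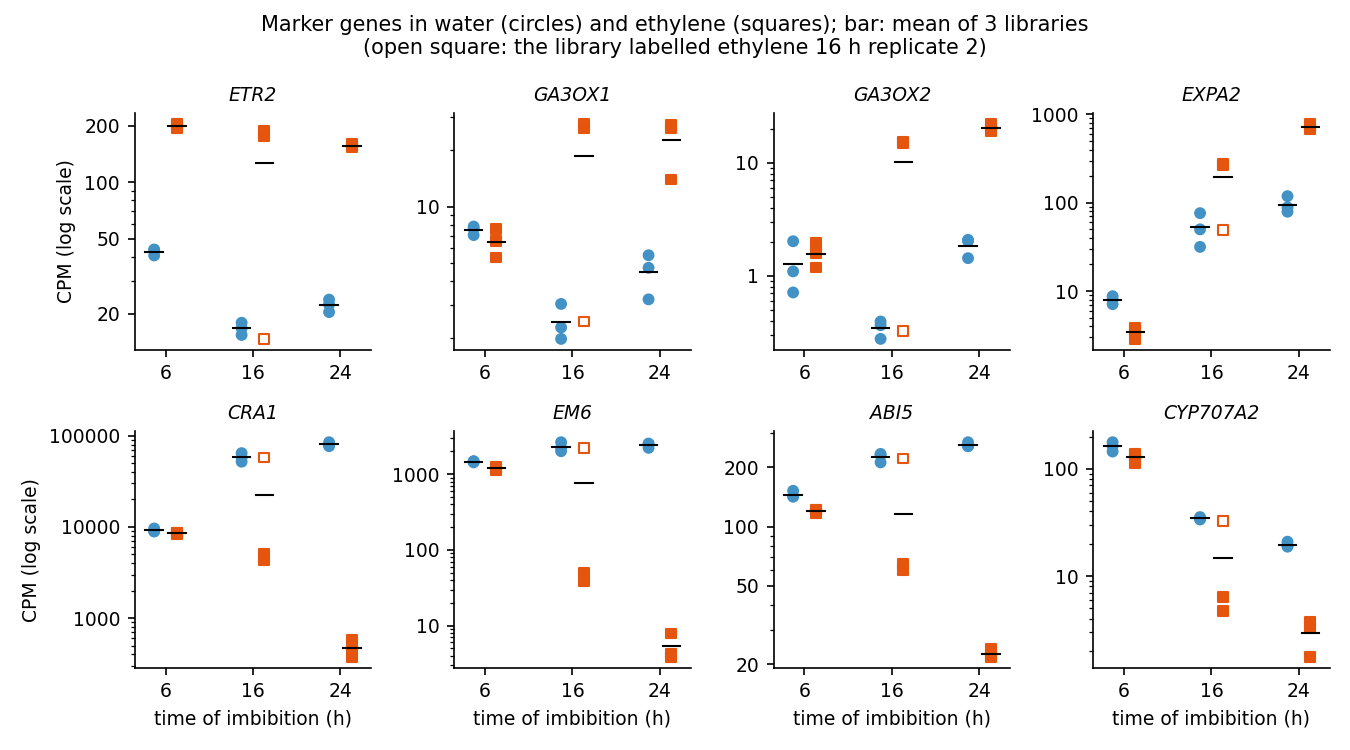
CPM of 8 genes on a log axis against hours of imbibition, with circles for water, squares for ethylene, an open square for the library labelled ethylene 16 h replicate 2 and a bar for the mean of 3 libraries. GA3OX2 separated from water after 6 h and stood at 20.2 ± 1.48 against 1.85 ± 0.36 CPM at 24 h, while ETR2 already stood at 199 ± 4.92 against 42.7 ± 1.68 CPM at 6 h.

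Other large increases at 24 h were GA2OX3, a gibberellin-inactivating gene at 14 ± 0.879 CPM and 0 in water (at least 229-fold), and the transporter gene UMAMIT11 (at least 79.9-fold, from 0). ARGOS rose 88.6-fold, its relative ORS1 78.8-fold and CYP71B29 43.8-fold. Large decreases were TSPO, a stress-induced membrane protein gene (508-fold), ATECP31 (475-fold), and PMAT2, a malonyltransferase gene at 0 with ethylene (at least 70.8-fold lower). HMT3, a homocysteine methyltransferase gene, had 2 counts with ethylene and 1030 in water, a ratio of 686 (189 to 5670).

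All 12 storage protein and oleosin genes fell (12 adjusted over the list alone; median -6.81, camera adjusted p = 4.22e-06), as did all 11 late embryogenesis abundant genes (11 adjusted over the list alone; median -7.11, camera adjusted p = 6.97e-05). Cell wall loosening genes rose in 18 of 20 and fell in 0 (18 and 0 adjusted over the list alone; median 2.28, camera adjusted p = 0.00933), with XTH31 at 931 ± 42.5 against 51 ± 8.48 CPM and EXPA9 rising 8.69-fold. Cell cycle and replication genes rose in 17 of 23 and fell in 1 (17 and 1 adjusted over the list alone; median 1.74, camera adjusted p = 0.0114), with PCNA1 at 42.4 ± 3.49 against 5.92 ± 0.687 CPM and CDT1A rising 6.61-fold. Genes of beta-oxidation and gluconeogenesis rose in 17 of 18 and fell in 1 (17 and 1 adjusted over the list alone; median 1.19, camera adjusted p = 0.000223), with CSY2, a peroxisomal citrate synthase gene, rising 7.2-fold and PCK1 3.43-fold. Low-oxygen response genes rose in 13 of 15 and fell in 1 (13 and 1 adjusted over the list alone; median 2.85, camera adjusted p = 0.00309), with HB1 at 110.2 ± 10.5 against 5.16 ± 1.05 CPM, the sucrose synthase gene SUS4 13.2-fold and the alcohol dehydrogenase gene ADH1 5.23-fold higher. Cytosolic ribosomal protein genes rose in 61 of 82 and fell in 10 (61 and 11 adjusted over the list alone; median 0.66, camera adjusted p = 0.00248). With an estimated correlation no list passed at 24 h, and these 7 had adjusted p = 0.494 with an estimated correlation, except the ribosomal list with adjusted p = 0.551. That correlation was estimated in the fit that keeps the library labelled ethylene 16 h replicate 2, so the share of that library in these values is left open.

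The lists of ethylene, abscisic acid and gibberellin held members of both directions at 24 h and none of them passed camera. In ethylene synthesis 7 of 9 rose and 2 fell (median 0.96, camera adjusted p = 0.343). ACO1 rose 31.2-fold and ACO5 by 5.32 on the log2 scale, while ACS2, which makes their substrate, fell 183-fold. In ethylene perception 10 of 14 rose and 2 fell (median 0.52, camera adjusted p = 0.416), with ERS1 8.66-fold, ETR2 7.04-fold and EBF2 1.19-fold higher and ERS2 at 22.5 ± 0.598 against 18.9 ± 0.781 CPM (adjusted p 0.206). Of 13 ethylene response factor genes 7 rose and 3 fell, with EDF3 35.3-fold and TEM1 7.53-fold higher (EDF3 at a log2 fold change of 5.14, and 5.82 without water 24 h replicate 3). In abscisic acid synthesis 6 of 8 fell and 2 rose (median -1.27, camera adjusted p = 0.169), with NCED9 21-fold, ABA1 9.26-fold and NCED6 3.79-fold lower. Of 3 abscisic acid catabolism genes 2 rose and 1 fell, with CYP707A3 3.4-fold higher and CYP707A2 6.72-fold lower. In abscisic acid signalling 13 of 25 rose and 11 fell, with the phosphatase genes HAI3 61-fold and AHG1 26.6-fold lower; the list's median of 0.15 was -0.09 when all 21 libraries set the scale, and camera placed it lower (adjusted p = 0.491).

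Of 10 gibberellin synthesis genes 3 rose and 4 fell at 24 h, with a median of -0.25 and a mean of 0.28. GA3OX1 rose 4.96-fold, while GA20OX3 fell from 483 ± 11.8 CPM to 103 ± 7.53 CPM. GA2OX2, the other tested gene of gibberellin inactivation beside GA2OX3, fell 29.7-fold. Of 12 gibberellin signalling genes 6 rose and 5 fell (median 0.26, camera lower, adjusted p = 0.466), with GASA6 14.4-fold higher, the receptor gene GID1A 5.25-fold lower and RGL2 1.8-fold lower. Of 13 dormancy regulators 4 rose and 8 fell (median -0.40, camera adjusted p = 0.115), with SOM at 39.4 ± 5.01 against 643 ± 9.14 CPM, SPT 5.99-fold higher, and DOG1, a dormancy gene, at 1 count with ethylene and 35 in water, a ratio of 46.6 (7.83 to 1890). In the photosynthesis list 10 of 19 rose and 5 fell (median 0.88, mean -0.08, camera adjusted p = 0.328), with RBCS3B 7.06-fold and PRK 7.86-fold higher. The 5 that fell included LHCB1.2, at 0.654 ± 0.136 against 44.9 ± 76.5 CPM, where water 24 h replicate 3 alone held 129.7 CPM; without that library its log2 fold change moved from -6.09 to -0.19 (adjusted p = 0.822 in edgeR's test), and 16 of the 19 genes rose and 0 fell, with a list median of 1.57, a camera adjusted p of 0.0115 and an adjusted p = 0.437 with an estimated correlation.

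At 24 h 8977 genes were called higher and 6020 lower of 18806 (edgeR), 5061 and 2754 of them by at least 2-fold, and 9565 and 6516 without the library labelled ethylene 16 h replicate 2. The median log2 fold change of all genes tested was 0.24, and with all 21 libraries in 1 fit the median was 0 and the counts were 7327 higher and 7503 lower, so fold changes at 24 h are relative to that shift.

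**Figure D3:**
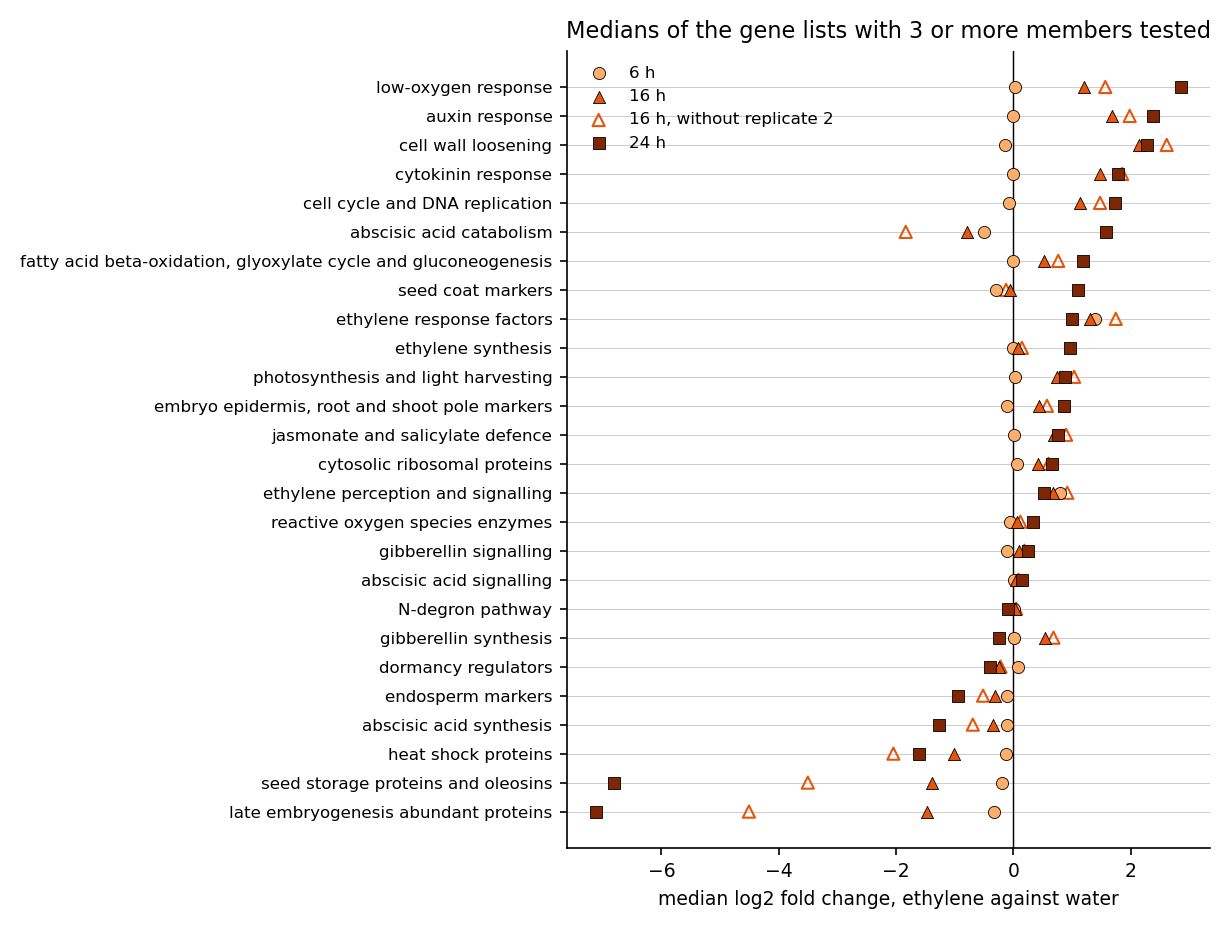
Median log2 fold change of ethylene against water for each of 26 gene lists at 6 h, 16 h, 16 h without the library labelled replicate 2, and 24 h, with 1 symbol per time. Late embryogenesis abundant and storage genes lie lowest at 24 h at -7.11 and -6.81, and low-oxygen genes highest at 2.85.

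The change of the ethylene effect between times was tested as an interaction. From 6 h to 24 h 6283 genes gained and 5057 lost relative to water (edgeR, 18806 tested), and 7472 and 5874 without the library labelled ethylene 16 h replicate 2. ATCSLA09, a mannan synthase gene, gained 7.42 ± 1.4 on the log2 scale (6.41 without water 6 h replicate 1), a value that depends on the prior count because it had 0 counts with ethylene at 6 h, while TSPO lost the most (-8.71 ± 1.6), followed by EM1 (-8.65 ± 1.47). The ethylene effect on ERS2 was smaller at 24 h than at 6 h (-1.95 ± 0.27), with ethylene at 22.5 ± 1.51 CPM at 6 h and 22.5 ± 0.598 CPM at 24 h and water at 4.89 ± 0.544 CPM and 18.9 ± 0.781 CPM, so the difference closed from the water side. That on EBF2 was also smaller (-0.54 ± 0.12), with ethylene at 626 ± 2.15 CPM and 244 ± 10.9 CPM and water at 361 ± 18.7 CPM and 205 ± 11.7 CPM, and ETR2 had a difference of 0.60 ± 0.74 (adjusted p 0.512). With all 21 libraries in 1 fit 4644 genes gained and 6509 lost.

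From 6 h to 16 h 50 genes gained and 36 lost, with gains of IGMT5 (AT1G76790) (3.71 ± 0.76), a methyltransferase gene, LTPG2 (3.28 ± 0.67) and CYP709B2 (3.08 ± 0.35), and losses of ERF2 (-2.02 ± 0.22) and the dormancy gene MFT (-1.87 ± 0.37). Without the library labelled ethylene 16 h replicate 2 these counts were 6258 and 5407. Leaving out any of the other 11 compared libraries gave 26 to 47 genes: ethylene 16 h replicates 1 and 3 gave 36 and 33, ethylene 6 h replicates 31, 28 and 37, water 16 h replicates 47, 35 and 26, and water 6 h replicates 30, 40 and 31. The compared groups alone gave 6 genes, DESeq2 1520, all 21 libraries 203 and an FDR of 0.01 left 22. From 16 h to 24 h 2197 genes gained and 2664 lost, among them SNG1, of phenylpropanoid metabolism (3.07 ± 0.18), and ATECP31 (-7.36 ± 1.5), or 3.17 and -3.33 without the library labelled ethylene 16 h replicate 2. The counts were 3884 and 3928 without the library labelled ethylene 16 h replicate 2, 3227 in all without water 16 h replicate 1, 2380 from the compared groups alone, 1896 at an FDR of 0.01, and 1269 and 4393 with all 21 libraries in 1 fit.

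Calls at 16 h and 24 h overlapped by 5606 genes higher at both times, where independent lists would share 2843, and 3042 lower at both, where they would share 1116. Calls at 6 h and 16 h shared 46 higher genes against 33.9 from independent lists (Fisher's exact test, 2-sided, p = 0.016) and 10 lower genes against 12.6 (p = 0.531). All overlap counts here keep the library labelled ethylene 16 h replicate 2. Without it 214 genes were at least 2-fold higher at 6 h, and at least 182 of these were also called higher at 16 h. The other overlaps were not computed without it. Calls at 6 h and 24 h shared 41 higher against 51.1 (Fisher's exact test, p = 0.0525) and 21 lower against 21.8 (p = 0.897). Of the 107 genes higher at 6 h, 41 were lower at 24 h, and of the 68 lower at 6 h, 35 were higher at 24 h. Of all 18806 genes tested, 6020 were called lower and 8977 higher at 24 h. For the opposite calls the number from independent lists was not computed, so they do not show a reversal. These p-values are unadjusted and rest on genes, which are not independent replicates.

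**Figure D4:**
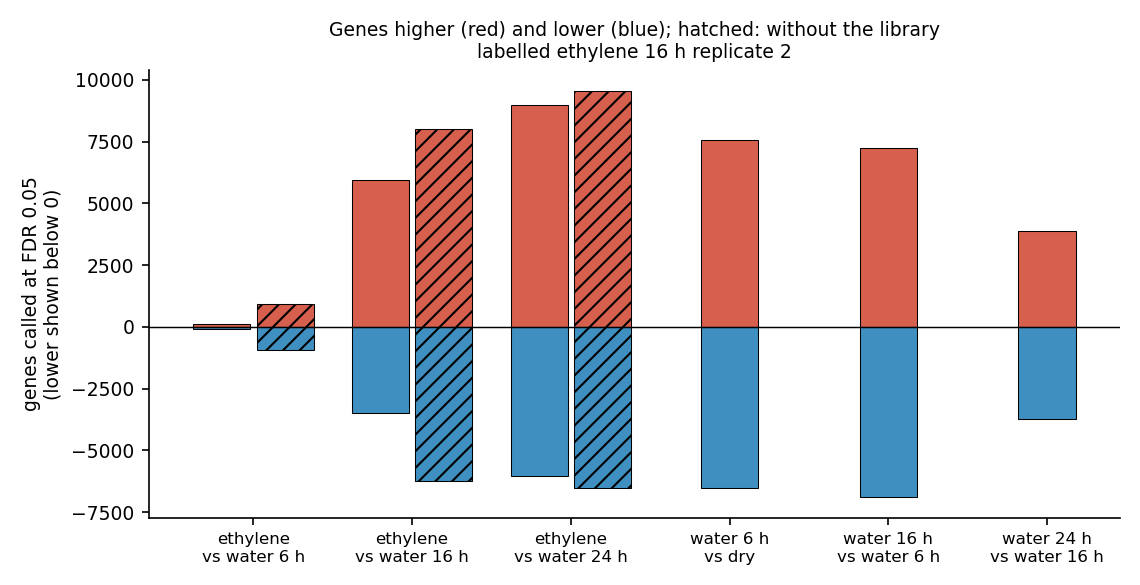
Number of genes called higher (red) and lower (blue) at an FDR of 0.05 by edgeR in 6 comparisons, with hatched bars for the 3 ethylene comparisons fitted without the library labelled ethylene 16 h replicate 2. At 6 h ethylene gave 107 and 68 genes with that library and 906 and 944 without it, and at 24 h 8977 and 6020 with it.

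Water at 6 h was compared with dry seeds, which served as the untreated starting point. Storage transcripts and most late embryogenesis abundant transcripts fell, and those of most ribosomal proteins rose. These lists passed camera at its preset correlation, but not with an estimated correlation (camera adjusted p = 0.56 each). DOG1 (AT5G45830) fell from 99.5 ± 5.16 CPM to 3.55 ± 0.0761 CPM and EM6 (AT2G40170) from 22342 ± 460.2 CPM to 1188 ± 17 CPM. TSO2 (AT3G27060), a ribonucleotide reductase subunit gene, rose from 5.72 ± 1.3 CPM to 720.2 ± 24.5 CPM, and the expansin gene EXPA10 from 0.124 ± 0.142 CPM to 61.1 ± 4.06 CPM. CPM values belong to the fit on dry and water libraries, whose scale differs from that of the ethylene comparisons. From 0 in dry seeds, the transcription factor gene NTL8 rose at least 883-fold, AATP1 at least 504-fold, ARAB-1 at least 138-fold and the microtubule protein gene MAP65-2 at least 125-fold. The sugar transporter gene SWEET6 fell 311-fold, the phosphatase gene HAI1 184-fold, the galactinol synthase gene GolS2 135-fold and the abscisic acid receptor gene PYL12 132-fold. HAI1 was at a log2 fold change of -7.52, and -8.34 without water 6 h replicate 2, and EXPA10 at 8.86, and 10.2 without dry replicate 1.

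Storage and oleosin genes fell in 12 of 12 (12 adjusted over the list alone; median -2.58, camera adjusted p = 5.11e-08), with OLEO4 13.9-fold and CRA1 5.48-fold lower. Late embryogenesis abundant genes fell in 10 of 11 (10 adjusted over the list alone; median -3.50, camera adjusted p = 1.64e-07), with RAB28 45.8-fold and LEA7 30.7-fold lower. Cytosolic ribosomal protein genes rose in 66 of 81 and fell in 13 (66 and 13 adjusted over the list alone; median 1.53, camera adjusted p = 2.42e-10), with RPSAb 28.8-fold higher. These 3 lists had adjusted p = 0.56 with an estimated correlation. Of 10 abscisic acid synthesis genes 8 fell and 1 rose (median -1.17, camera adjusted p = 0.0984), with NCED3 at 0 in water (at least 130-fold lower) and NCED6 19.3-fold lower. CYP707A2 rose 3.13-fold and CYP707A1 fell 20.9-fold. Of 10 gibberellin synthesis genes 7 rose and 2 fell (median 4.71, or 2.54 with members at 0 set to their bound; camera adjusted p = 0.304), with GA3OX1 at 376 counts against 1, a ratio of 194 (34.6 to 7670), and GA3OX2 at least 11-fold higher from 0. The inactivation gene GA2OX6 fell 92-fold. Of 20 cell wall genes 13 rose and 1 fell (median 3.69, or 2.07 with members at their bound; camera adjusted p = 0.107), with EXPA8 259-fold higher. EXPA2 rose from 0.3715, 0 and 0 CPM in the 3 dry libraries to 6.44 ± 0.694 CPM, a log2 fold change of 5.63 that rests on those few counts, and of 9.996 without dry replicate 1. Of 13 dormancy regulators 8 rose and 4 fell (median 1.37, camera adjusted p = 0.706), with DOG1 among those that fell. The list was not split by whether its genes promote or oppose dormancy, so these counts do not show whether genes that act like DOG1 fell.

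ERS1 rose 31.4-fold and ETR2 10.3-fold on imbibition, while ERS2 fell 2.97-fold and ACS2 17.7-fold, and EBF2 was at 292 ± 15.7 against 317 ± 18.4 CPM (adjusted p 0.062 by edgeR). RGL2 rose 11.1-fold, HB1 65.4-fold (log2 fold change 6.03, and 6.86 without dry replicate 3) and MAN7 3.61-fold. ABI5 fell 10.3-fold, ADH1 6.32-fold, the seed heat shock factor gene HSFA9 21.2-fold and the peroxiredoxin gene PER1 22.4-fold. In all, 7554 genes were called higher and 6505 lower of 17782 (edgeR), 4319 and 3547 by at least 2-fold. The median log2 fold change of all genes was 0.11, and 0.22 under upper-quartile scaling.

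From 6 h to 16 h in water, heat shock transcripts fell, while storage and oleosin genes went both ways, with 3 of 12 higher and 4 lower (median -0.15, camera adjusted p = 0.826). The plastid heat shock gene HSP21 (AT4G27670) fell from 49.6 ± 2.89 CPM to 0.0842 ± 0.00496 CPM and the mitochondrial HSP23.6-MITO from 1287 ± 50.1 CPM to 6.51 ± 0.978 CPM. CRA1 rose from 7411 ± 298 CPM to 46693 ± 4833 CPM and RAB28 8.35-fold, while DOG1 fell to 0.434 ± 0.0833 CPM and CYP707A2 from 131 ± 12.4 CPM to 27.8 ± 0.758 CPM. The arabinogalactan gene AGP31 had 1598 counts against 1, a ratio of 1390 (250 to 55100), and NAI2, of endoplasmic reticulum bodies, 1105 against 2, a ratio of 482 (133 to 3980). The glucosidase gene PYK10 rose 276-fold and the protease gene SBT1.3 208-fold, while HSP17.6II fell 461-fold and PMZ 128-fold. PYK10 was at a log2 fold change of 8.11, and 8.96 without water 6 h replicate 3.

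Heat shock genes fell in 12 of 12 (12 adjusted over the list alone; median -5.63, camera adjusted p = 1.88e-08, adjusted p = 0.0919 with an estimated correlation). Low-oxygen genes fell in 11 of 15 and rose in 1 (11 and 1 adjusted over the list alone; median -1.52, camera adjusted p = 0.000658, adjusted p = 0.0919 with an estimated correlation), with HB1 30.9-fold and ADH1 6.05-fold lower. Ethylene perception genes fell in 10 of 13 and rose in 2 (10 and 2 adjusted over the list alone; median -0.72, camera adjusted p = 0.009, adjusted p = 0.0919 with an estimated correlation), with EIN4 3.01-fold, ETR2 2.57-fold and EBF2 1.76-fold lower and ERS2 2.96-fold higher. Beta-oxidation and gluconeogenesis genes fell in 17 of 18 and rose in 1 (17 and 1 adjusted over the list alone; median -0.74, camera adjusted p = 3.02e-05, adjusted p = 0.541 with an estimated correlation), with ACX2 4.34-fold lower. Cytosolic ribosomal protein genes rose in 60 of 81 and fell in 13 (60 and 13 adjusted over the list alone; median 0.55, camera adjusted p = 1.64e-06, adjusted p = 0.541 with an estimated correlation).

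NCED6 rose 12.8-fold from 6 h to 16 h in water, the gibberellin inactivation gene GA2OX2 10.4-fold, MFT 5.76-fold, RGL2 1.9-fold, ABI5 1.54-fold and EM6 1.56-fold. GA3OX1 fell 3.1-fold, GA3OX2 3.39-fold and the cytokinin oxidase gene CKX5 11.3-fold. Of 20 cell wall genes 9 rose and 4 fell, with XTH31 at 450 counts against 3, a ratio of 131 (44.5 to 637), EXPA4 36.7-fold (log2 fold change 5.2, and 6.4 without water 6 h replicate 3), EXPA2 6.5-fold and MAN7 4.51-fold higher. RBCS1A, a Rubisco subunit gene, rose 21.5-fold. In all, 7258 genes were called higher and 6905 lower of 17782 (edgeR), 3534 and 2637 by at least 2-fold, with an all-gene median of 0.03, and 0.17 under upper-quartile scaling. That scaling turned the medians of gibberellin synthesis (-0.02 to 0.12) and abscisic acid synthesis (-0.05 to 0.09). Under the main scaling the abscisic acid synthesis median was -0.18 with the member at 0 set to its bound.

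From 16 h to 24 h in water most of the 2-fold changes were increases. PORB (AT4G27440), of chlorophyll synthesis, rose from 0.338 ± 0.294 CPM to 22.7 ± 1.79 CPM, the glucosidase gene BGLU21 to 17.9 ± 3.2 CPM and the gibberellin-stimulated GASA4 to 20.4 ± 3.47 CPM. ACO1 rose from 2.31 ± 1.25 CPM to 25.1 ± 3.51 CPM and the epidermal gene PDF1 from 20.0 ± 2.71 CPM to 80.8 ± 6.06 CPM. Without water 16 h replicate 1 the log2 fold change of PORB moved from 6.04 to 7.02 and that of BGLU21 from 6.55 to 9.32, and without water 16 h replicate 3 BGLU21 was at 5.94. The light-harvesting gene LHB1B2 stood at 53 ± 90.4 against 0.085 ± 0.0459 CPM, with 188.3 CPM in replicate 3 alone, and its log2 fold change moved from 9.24 to 3.45 without that library. HSP22.0 fell 15.6-fold and the chitin-binding protein gene PR4 5.19-fold, and PYL11 had 3 counts against 34, a ratio of 9.59 (3.02 to 48.8).

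Photosynthesis genes rose in 14 of 14 (14 adjusted over the list alone; median 2.69, camera adjusted p = 3.23e-10, adjusted p = 0.144 with an estimated correlation). Without water 24 h replicate 3 the list rose in 14 of 15, with a median of 1.42, and an adjusted p = 0.00375 with an estimated correlation, and log2 fold changes of LHCB5 and LHCA2 moved from 5.25 and 4.79 to 1.38 and 2.32. Cell wall genes rose in 13 of 20 and fell in 2 (14 and 3 adjusted over the list alone; median 0.72, camera adjusted p = 0.000105, adjusted p = 0.583 with an estimated correlation), with XTH4 17-fold and EXPA2 1.84-fold higher. Low-oxygen genes rose in 11 of 15 and fell in 2 (11 and 2 adjusted over the list alone; median 0.53, camera adjusted p = 0.00176, adjusted p = 0.144 with an estimated correlation), with SAD6 24.6-fold and SUS4 at least 17.2-fold higher from 0. Ethylene synthesis genes rose in 6 of 9 and fell in 0 (6 and 0 adjusted over the list alone; median 0.45, camera adjusted p = 0.00615, adjusted p = 0.383 with an estimated correlation), with ACO5 12.6-fold higher. Without water 16 h replicate 1 log2 fold changes were 4.83 for ACO5 and 5.34 for SAD6, against 3.65 and 4.62. Storage genes fell in 8 of 12 and rose in 2 (9 and 2 adjusted over the list alone; median -0.24, camera adjusted p = 0.0164, adjusted p = 0.635 with an estimated correlation), with the albumin gene SESA3 1.86-fold lower and CRA1 1.4-fold higher. Ribosomal protein genes fell in 36 of 81 and rose in 8 (36 and 8 adjusted over the list alone; median -0.13, camera adjusted p = 0.00167, adjusted p = 0.635 with an estimated correlation).

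Endosperm marker genes fell in 3 of 5 and rose in 0 (4 and 0 adjusted over the list alone; median -0.43, camera adjusted p = 0.0304, adjusted p = 0.305 with an estimated correlation), with EPR1 1.82-fold lower. The storage and endosperm calls were lost without water 16 h replicate 3 (camera adjusted p = 0.0825) and water 24 h replicate 3 (camera adjusted p = 0.0514). CYP707A1 rose 4.03-fold and CYP707A3 3.49-fold while CYP707A2 fell 1.73-fold, and the abscisic acid response factor gene ABF3 rose 5.31-fold. GA3OX2 rose 5.19-fold, GA3OX1 1.92-fold, the cyclin gene CYCD3;1 5.36-fold, ETR2 1.34-fold, ERS2 1.32-fold, ABI5 1.17-fold and ADH1 1.24-fold. Log2 fold changes of genes not called were 0.32 for NCED6, 0.41 for DOG1, 0.09 for EM6, 0.01 for EBF2 and -0.01 for RGL2. In all, 3888 genes were called higher and 3713 lower of 17782 (edgeR), 1186 and 130 by at least 2-fold, and with all 21 libraries in 1 fit 3525 genes were called.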

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

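Of the tests in this part, those of a wrong label, of mixed seeds, of green tissue (restated for replicate 3) and of another plant were chosen only after the results were seen, and the others on single libraries after the comparisons of genes but before their own values. The results listed first were picked because the effect of ethylene differed between times in a test of that difference (edgeR interaction, log2 differences ± SE).

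From 6 h to 16 h 86 genes differed. The largest gains were IGMT5 (3.71 ± 0.76), the lipid transfer protein gene LTPG2 (3.28 ± 0.67), CYP709B2 (3.08 ± 0.35) and the wax synthesis gene KCS6 (2.77 ± 0.56). The largest losses were SAUR36 (-2.07 ± 0.38), ERF2 (-2.02 ± 0.22), MFT (-1.87 ± 0.37) and PIL2 (-1.71 ± 0.31). The count was 11665 without the library labelled ethylene 16 h replicate 2, of which 2588 gained and 1852 lost at least 2-fold. In that fit IGMT5 was at 4.22, CYP709B2 at 3.36 and ERF2 at -1.92. The ranking above belongs to the fit with that library and was not made without it. From 6 h to 24 h 11340 genes differed. The largest gains were ATCSLA09, a mannan synthase gene (7.42 ± 1.4), LTL1 (6.54 ± 1.82) and UGT72E2 (6.14 ± 1.89), and the largest losses TSPO (-8.71 ± 1.6), EM1 (-8.65 ± 1.47), HMT3 (-8.65 ± 1.97) and EM6 (-8.53 ± 1.56). The 3 gains rest on genes with 0 counts with ethylene at 6 h, so their fitted values depend on the prior count. Without water 6 h replicate 2 UGT72E2 was at 2.44 and not called, without replicate 3 UGT72E2 was at 6.74 and LTL1 at 7.15, and without replicate 1 ATCSLA09 was at 6.41. HMT3 was at -11.1 without ethylene 24 h replicate 1. From 16 h to 24 h 4861 genes differed, with gains of GSTU22 (4.24 ± 0.62), HSP18.2 (3.13 ± 0.97), SNG1 (3.07 ± 0.18) and CYP81F3 (3.04 ± 0.38) and losses of HMT3 (-7.5 ± 2.07), ATECP31 (-7.36 ± 1.5), PMAT2 (-7.35 ± 2.39) and TSPO (-7.35 ± 1.56). Without the library labelled ethylene 16 h replicate 2 the last 4 were at -3.12, -3.33, -3.9 and -3.33, so the size of these losses rests on that library. GSTU22, HMT3 and PMAT2 rest on groups with 3 or fewer counts, and their fitted values depend on the prior count. GSTU22 was at 3.63 without water 16 h replicate 3. HSP18.2 was at 2.45 without water 16 h replicate 1, 4.33 without the library labelled ethylene 16 h replicate 2 and 4.01 without water 24 h replicate 1, and it was not called without water 16 h replicate 1, ethylene 24 h replicate 2 or 3 or water 24 h replicate 2 or 3.

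The library labelled ethylene 16 h replicate 2 stood with the water 16 h libraries. The 5513 and 182 genes used below were chosen in the fit without it. On an axis from the mean of water (0) to the mean of the other ethylene 16 h libraries (1) over 5513 genes it lay at -0.002, within the -0.072 to 0.103 of single water libraries, which argues against a mixture of treated and water seeds. Over 182 genes that ethylene raised from 6 h on it lay at -0.038, within the water range of -0.063 to 0.088, which argues against seeds that perceived ethylene and responded later. A wrong label, or seeds that ethylene did not reach, needs a position of -0.002 within that range and may account for it, and these 2 were not told apart. The chi-square per degree of freedom of this library against water 16 h replicate 2 was 1.39, below the 1.69 of the closest pair within any group. No water 16 h library lay with the ethylene libraries, so an exchange between these groups has no partner, and beyond the later response no biological explanation was tested.

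Light-harvesting transcripts stood out in water 24 h replicate 3. Among genes above a minimum read number there, 18 lay at least 4-fold above both other libraries, and 10 of them belong to the photosynthesis list. LHCB1.2 was at 129.7 CPM against 0.17 and 1.15, and LHB1B2 at 188.3 against 0.17 and 1.89, while the Rubisco gene RBCS1A was at 462 against 449 and 463. Green tissue of this species would bring other abundant leaf transcripts, but only 1 of 10, GAPA at 41.6 CPM, lay 2-fold above both other libraries. Of the 10, 7 have at least 10 CPM in these seeds, and of the rest CA1 was at 0, TGG2 at 0.0516 and ESM1 at 0.155 CPM. Outside these 10, RCA was at 143.6 against 39.9 and 43.7 CPM and GAPA-2 at 15.9 against 2.14 and 2.15. FNR2, PSBP-2 and PSAH-1 also lay at least 4-fold above both other libraries, while RBCS2B, RBCS3B and PSBO1 did not reach 2-fold. The result thus depends on which leaf transcripts are counted. Light before harvest would raise light-induced genes, and 0 of 8 were 2-fold higher, of which 1 has at least 10 CPM in the other libraries. Reads of another plant, of which conserved genes map, may account for it, since 2.04% of this library's reads were unmapped, against at most 1.0% elsewhere, but this stays open. The 1.0% was that of water 24 h replicate 2, also above the other 19 libraries (at most 0.548%), where LHCB1.2 was at 1.15 CPM against 0.17 in replicate 1 and chloroplast genes had the most counts, 3582 against 1470 in replicate 3 and 807 in the shallower replicate 1. Chloroplast counts thus did not follow the pattern, unmapped reads were also raised in a library with little of it, and beyond light no biological explanation was tested.

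Other splits of the compared libraries were refitted. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. At 6 h the real split called 175 genes and the highest other 0 (1 of 10 splits as large), and at 24 h 14997 and 0 (1 of 10). Water at 6 h against dry gave 14059 and 0 (1 of 10), water at 16 h against 6 h 14163 and 0 (1 of 10), and water at 24 h against 16 h 7601 and 0 (1 of 10). At 16 h 2 of 10 splits were as large, the real one with 9440 genes and 1 with 10797, which placed ethylene replicates 1 and 3 with water replicate 1 and so follows the structure described for that library. For changes between times 60 splits of the 12 compared libraries were refitted. These splits also break up the ethylene effect at each time, so they do not show what no change between times would give, and chance was left open in all 3. For the change from 6 h to 24 h the real split called 13257 genes and the highest other 12877 (1 of 60), a split that kept the ethylene 24 h libraries together. For 6 h to 16 h the values were 6 and 77 (3 of 60) and from 16 h to 24 h 2380 and 6612 (6 of 60), where splits with many more genes point to a structure of the samples.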

How the results depend on the processing

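Fits without the library labelled ethylene 16 h replicate 2 at 6 h and 24 h, unstranded counts and the photosynthesis list without water 24 h replicate 3 were chosen after the data were seen, and the other alternatives before. Of 279 named log2 fold changes 253 passed the threshold, 68 of these lost it under some alternative and 0 changed sign; of 174 counts of genes under alternatives 133 stayed within 1.5 times. Unless construction shows it (fewer libraries, a stricter threshold), the cause was not tested. The genes called at 6 h (175) were 79 at an FDR of 0.01, 301 and 302 by DESeq2 without and with independent filtering, 2325 from the compared groups alone and 84 to 1850 leaving out a library. At 16 h (9440) they were 2311 at an FDR of 0.01, 0 from the compared groups alone by edgeR (3267 at an unadjusted p under 0.05) and 1064 to 14267 leaving out a library; at 24 h (14997) 14267 to 16081. The change from 6 h to 16 h (86) gave 22 at an FDR of 0.01, 203 with all 21 libraries, 1520 and 1677 by DESeq2, 6 from the compared groups and 26 to 11665 leaving out a library. The change from 6 h to 24 h (11340) gave 10339 to 13346, and that from 16 h to 24 h (4861) 1896 at an FDR of 0.01, 2380 from the compared groups and 3227 to 7812 leaving out a library. Leaving out a library gave 13739 to 13975 for water at 6 h against dry, 13693 to 13866 for 16 h against 6 h and 6478 to 6909 for 24 h against 16 h, which had 3525 with all 21 libraries (main 7601).

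Replicate numbers did not pair the libraries: in 0 of 21 pairs of groups did every same-number correlation exceed 0.1 (-0.495 to 0.53), and in 20 of 63 comparisons of a library with another group (each library counted several times) the best correlation was with its own number. With the replicate block 133, 9324 and 14811 genes were called at 6, 16 and 24 h and 45 for the change from 6 h to 16 h. Shared calls at an FDR of 0.01 were 16 higher and 0 lower for 6 h with 16 h (edgeR; DESeq2 shared 17 lower at an FDR of 0.05), 19 and 7 for 6 h with 24 h and 2106 and 77 for 16 h with 24 h. At an FDR of 0.05 DESeq2 without independent filtering gave 93 and 17 for 6 h with 16 h, where independent lists would share 57.2 and 25.7, and 85 and 35 for 6 h with 24 h, against 82.6 and 39.8. The higher genes of 6 h and 24 h thus lay below that number by edgeR (41 against 51.1) and above it by DESeq2. Camera called 2, 8 and 10 lists at 6, 16 and 24 h and 3, 5 and 7 in the water steps. With an estimated correlation it called 1, 0, 0, 0, 0 and 0 (34 of 35 calls lost), and fry called 4, 14, 25, 24, 21 and 19. For the ethylene comparisons the estimate came from the fit that keeps the library labelled ethylene 16 h replicate 2, so these losses are not told apart from an effect of that library. The water steps lost their calls in a fit that does not hold it. Leaving out a library gave 2 to 8, 6 to 9 and 9 to 11 lists at 6, 16 and 24 h (5 at 6 h without ethylene 6 h replicate 1). Camera calls lost at 16 h were perception (adjusted p = 0.0735 and 0.0532 without water 16 h replicates 1 and 2), cell wall (0.0543 without replicate 3) and auxin (0.0541, 0.0532 and 0.0543 without replicates 1, 2 and 3), and at 24 h embryo markers (0.0506 with RLE factors to 0.0667 without the library labelled ethylene 16 h replicate 2).

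Among the 279 log2 fold changes run through the alternatives, signs turned only in 3 genes not called. Not every fold change named in the text was among them. NCED6 in the change from 6 h to 24 h ranged from -0.00905 to 0.8912 leaving out a library. EBF2 in water from 16 h to 24 h was -0.002796 with no filter and -0.02287 to 0.04518 leaving out a library. RGL2 there was 0.02364 with RLE and 0.03229 with upper-quartile factors, 0.02602 with the stricter filter, 0.02396 by DESeq2, 0.004942 from the compared groups and -0.02683 to 0.0155 leaving out a library. List medians near 0 turned with scaling: N-degron genes at 16 h from 0.03 to -0.02 with all 21 libraries, and from -0.06 to 0.04 in water at 6 h against dry with upper-quartile factors. Depth limits low genes most in water 24 h replicate 1 and water 6 h replicate 1, with 12154732 and 13646486 reads.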

Other observations

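No test in this part was chosen after its own result was seen, but the 2 correlations at the end were set after the comparisons of genes had been seen. At 24 h auxin response genes rose in 14 of 17 and fell in 1 (14 and 1 adjusted over the list alone; median 2.39, camera adjusted p = 0.0215, adjusted p = 0.494 with an estimated correlation), with GH3.3, which conjugates auxin, 36.4-fold, the repressor gene IAA19 12.2-fold and YUC8, of auxin synthesis, 27.4-fold higher. GH3.3 was at a log2 fold change of 5.19, 6.0 without water 24 h replicate 2 and 4.53 without water 24 h replicate 3. At 16 h IAA7 had 48 counts with ethylene and 3 in water, a ratio of 14.5 (4.66 to 72.6). Of 7 cytokinin genes 4 rose and 1 fell at 24 h (4 and 1 adjusted over the list alone; median 1.79, camera adjusted p = 0.475), with the response regulator gene ARR4 6.9-fold higher and the cytokinin oxidase gene CKX3 6.2-fold lower. Of 15 reactive oxygen enzyme genes 9 rose and 6 fell (9 and 6 adjusted over the list alone; median 0.34, mean -0.02, camera adjusted p = 0.72). The peroxiredoxin gene PER1 fell 107-fold and the catalase gene CAT3 9.92-fold, while the ascorbate peroxidase gene APX1 rose 6.62-fold and the superoxide dismutase gene FSD1 4.98-fold. Of 5 jasmonate and salicylate genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.77, camera adjusted p = 0.72), with JAZ1 4.25-fold higher and AOS 6.79-fold lower.

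Heat shock genes fell in 9 of 12 and rose in 1 at 24 h (9 and 1 adjusted over the list alone; median -1.61, camera adjusted p = 0.00875, adjusted p = 0.494 with an estimated correlation), led by the seed factor gene HSFA9 (278-fold) and HSP17.6A (19.8-fold). Of 11 N-degron genes 4 rose and 4 fell (3 and 4 adjusted over the list alone; median -0.08, camera adjusted p = 0.475), with EBP 5.21-fold lower and VRN2 1.93-fold higher. Embryo epidermis, root and shoot pole genes rose in 8 of 10 and fell in 0 (8 and 0 adjusted over the list alone; median 0.86, camera adjusted p = 0.0498, and 0.0506 to 0.0667 where the call was lost, adjusted p = 0.522 with an estimated correlation), with PDF1 3.55-fold and SHR 2.77-fold higher. Of 5 endosperm genes 2 rose and 3 fell (2 and 3 adjusted over the list alone; median -0.95, camera adjusted p = 0.379), with EPR1 8.16-fold lower and FWA 2.16-fold higher. Of 5 seed coat genes 3 rose and 0 fell (3 and 0 adjusted over the list alone; median 1.1, camera adjusted p = 0.179), with TTG2 4.28-fold and MUM4 3.13-fold higher.

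Seeds with ethylene at 24 h might lie at a stage that seeds in water had at 6 h, which needs their ethylene effect to oppose the change in water from 6 h to 16 h. The ethylene effect was taken from the fit without the library labelled ethylene 16 h replicate 2. Across 17632 genes that effect and the change in water correlated at r = -0.041 (rho = -0.064), against an r below -0.3 if so, and 55.6% of the 12033 genes called in both had opposite signs, which argues against that stage. The change from dry seeds to 6 h in water could be partly undone by 24 h. Across 15480 genes the change from dry to water 6 h replicate 1 and that from water 6 h replicates 2 and 3 to 24 h correlated at r = -0.12 (rho = -0.108), between the bounds of -0.3 and -0.1 set for and against it, so this stays undecided. Genes are not independent replicates.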
